A study of Xenopus laevis with 12 samples.

How the data were processed

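Gene expression was measured by strand-specific poly-A RNA sequencing of whole Xenopus laevis embryos at stage 9.5. Per the labels, each replicate was RNA from 3 embryos, and each library was made from 60 ng of total RNA. The 12 libraries were assigned to control, genistein, BIO and Chiron by their treatment labels, 3 to a group, and all 12 columns of the deposited table could be matched to a sample by name. The authors deposited 1 table of whole-number read counts per gene, not normalized, with 18892 genes. Per the submitters' processing notes STAR 2.5.2b and edgeR were used, with no role or order given. The genome build, annotation and counting tool, and any filter on rare genes, are not given in the sources used here. Of the genes, 99.8% reached 0.5 CPM in 3 libraries.

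The table names genes by symbol, with 9063 L homeologs, 6846 S homeologs and 2983 other names. A table of RefSeq genes of the Xenopus laevis 10.1 assembly held 17504 of the 18892 names as symbols, among them 2674 of the 2676 names that start with LOC. Of the deposited names, 14 carry the prefix of gene models of that assembly. The RefSeq table was used only for gene names and for the relative length of the genes along the genome, and no coordinates are reported.

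Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as input, which left 18791 and removed 101. Library sizes were scaled by TMM, 1 quasi-likelihood negative binomial model was fitted to all 12 libraries with a mean per group, and 6 contrasts were tested with glmQLFTest: each compound against control, and each pair of compounds. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. The common biological coefficient of variation was 22.4%. Log2 fold changes are given with the standard error implied by the F statistic, and expression as the mean ± SD of 3 libraries in CPM. Where a group had 0 counts in all libraries, the fold was computed against a floor of 3 counts over the group and is a lower bound. Where it had 1 to 3 counts, the ratio of the groups has an exact (Clopper-Pearson) 95% interval. Floors and intervals cover counting error only.

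The following choices were made before the data were examined: the test, the contrasts, the 17 gene lists, the first set of other settings listed at the end, and the rule for named genes. For each compound against control the rule takes the 6 higher and 6 lower genes with the largest fold change. It asks for a call, a mean of at least 1 CPM, a symbol, and all 3 treated libraries on the same side of all 3 controls. It adds up to 2 called members of each list with the smallest p. In all cases it names sia1, sia2, nodal3, gsc, chrd, axin2, sp5, wnt8a, ventx1 and ventx2 (axin2 matched no gene of the table). Between compounds it takes the 4 higher and 4 lower. A comparison with no call names the 10 symbols with the smallest p. Some genes that the rule takes are not reported here.

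The lists covered early Wnt dorsal targets, organizer genes, zygotic Wnt targets, Wnt pathway components, BMP and ventral genes, mesendoderm and Nodal genes, epidermis, neural ectoderm, FGF and MAPK targets, maternal and germ plasm genes, the cell cycle, p53 and stress, targets of the aryl hydrocarbon receptor, NRF2 targets, estrogen response, ribosomal proteins and mitochondrially encoded genes. Not all members are targets: the aryl hydrocarbon receptor list also held the receptor gene ahr and its partner arnt, and the FGF and MAPK list also held FGF ligands and receptors. Members were matched by base symbol, so each homeolog and tandem copy counts as 1 gene. Calls were counted over all genes and again adjusted over the list alone. Lists were tested against other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 17 lists within a contrast, and again with the correlation estimated from the data. With the estimated correlation no list was called in any of the 6 contrasts of this fit. The test fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 4 lists in genistein against control, all lower (zygotic Wnt targets, neural ectoderm, FGF and MAPK, and aryl hydrocarbon receptor). It called 0 in BIO or Chiron against control and 0 between them. Against BIO it called 10 lists lower and 1 higher in genistein, and against Chiron 8 lower.

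Overlaps and correlations between compounds were set beside 10 simulations of unchanged groups that share the 3 controls, and beside the overlap of independent lists. The pipeline was tested on simulated counts for 18791 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For genistein, BIO and Chiron against control it recovered 52%, 46% and 45% of the 2-fold changes and 87%, 89% and 89% of the 4-fold changes. The fit with the mitochondrial share as covariate recovered 85%, 81% and 79%, and 96%, 98% and 98%. False calls among the unchanged genes numbered 4, 9 and 7 in the 4-group fit and 15, 22 and 12 with the covariate. Genes were drawn independently, so variation that a library shares across genes was simulated only as far as the covariate carries it. These numbers are therefore not the error rate for the real libraries. There, 1 split of the genistein and control libraries that was not by treatment called 9146 genes in the 4-group fit. Replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom of 2.28 to 200, so no replicate was a copy of another in its group.

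Other settings tried were the replicate number as a block, DESeq2 1.42.0, limma-voom, RLE size factors, scaling by library totals only, no count filter, a filter of at least 1 CPM in 3 libraries, only the 6 libraries compared in the fit, an absolute log2 fold change of at least 1, summed homeologs, and each library left out in turn. After the data were seen, a fit with log2 of the percent of counts on the 12 mitochondrially encoded genes as covariate was added, with a biological coefficient of variation of 11.0%, and a fit without control 1, genistein 1 and genistein 3.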

Results

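Whole embryos of the frog Xenopus laevis were profiled by poly-A RNA sequencing at stage 9.5, which the labels call early gastrula. The 12 libraries fell into 4 groups of 3: control, genistein, BIO and Chiron. Genistein is a soy isoflavone known as an inhibitor of tyrosine kinases. BIO, an indirubin derivative, and Chiron inhibit GSK3, the kinase that marks beta-catenin for destruction, and so activate Wnt signalling. Genistein was given at the 4-cell stage, per the series text. Doses, what the control embryos received, and the stage at which BIO and Chiron were given are not given in the sources used here, so the compounds cannot be called dose-matched. The comparisons ask how genistein changed the embryo's gene expression, and how that response stood beside those to a pair of known Wnt activators.

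Counts were given for 18892 genes. The library totals were 13158728, 14799872 and 13562406 counts in control replicates 1 to 3, and 13259764, 12130718 and 11091927 in genistein replicates 1 to 3. They were 13666222, 14593536 and 14090722 in BIO, and 15486533, 15122188 and 14380286 in Chiron. A gene with 0 counts in 1 library could still be present at 0.194 to 0.270 CPM (counts relative to library size), a limit that covers counting error only. Each replicate pooled 3 embryos. The labels do not say that the replicates came from separate clutches, so the p-values measure only the spread between these samples, which may be technical. Many genes exist as an L and an S homeolog, the copies left by the species' genome duplication, and 5227 base symbols were present as both. Reads shared between homeologs, or between tandem copies such as those of nodal3 and ventx, could be split by the counting, so values of single copies are uncertain to that extent.

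The libraries differed within groups in their content of mitochondrially encoded transcripts. These took 13.5%, 0.946% and 4.23% of the counts in control replicates 1 to 3, and 14.1%, 1.46% and 8.37% in genistein replicates 1 to 3. In BIO they took 0.553%, 2.66% and 0.841%, and in Chiron 0.999%, 1.40% and 1.62%. The group means were 6.24% ± 6.54 (SD, n = 3) in control, 7.96% ± 6.31 in genistein, 1.35% ± 1.14 in BIO and 1.34% ± 0.313 in Chiron. Ribosomal protein transcripts took 0.452%, 0.517% and 0.453% in control 1, genistein 1 and genistein 3, and between 0.178% and 0.266% in the other 9 libraries. The same 3 libraries stood apart on principal component 1, which held 57.4% of the variance, at -60.9, -93.2 and -68.0 against 1.11 to 37.2 elsewhere. Counts of called genes were therefore also taken with the mitochondrial share as a covariate and without those 3 libraries, alternatives chosen after the data were seen. Without them genistein 2 stands alone in its group and is assumed to vary like the other groups.

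**Figure D1:**
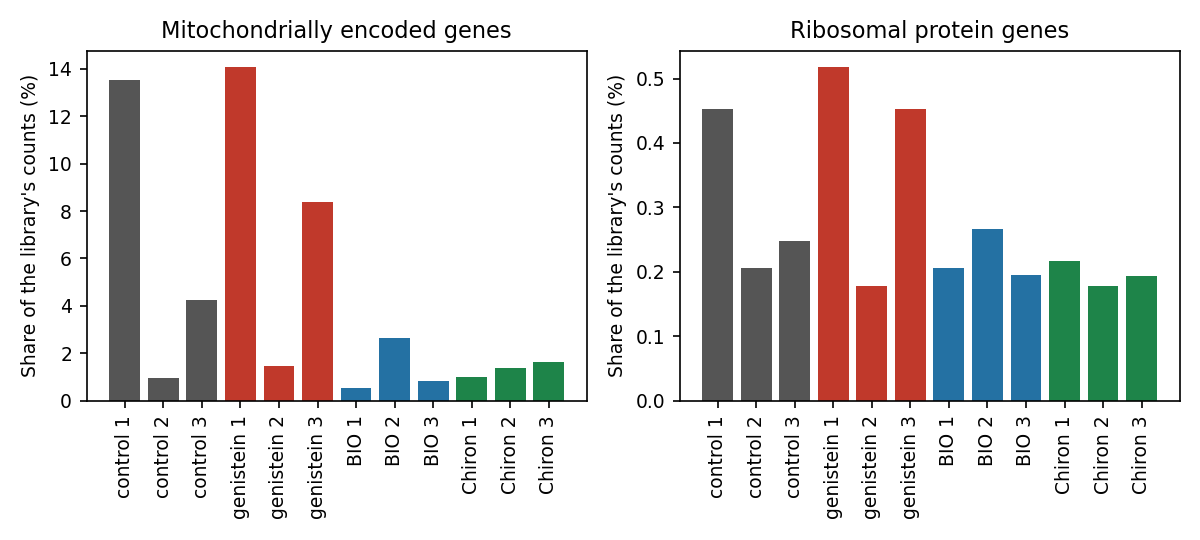
Percent of all counts on mitochondrially encoded genes (left panel) and on ribosomal protein genes (right panel) in each of the 12 libraries, 1 bar per library, coloured by group. Control 1, genistein 1 and genistein 3 hold 13.5%, 14.1% and 8.37% mitochondrial counts, and no BIO or Chiron library exceeds 2.66%.

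In genistein against control 68 genes rose and 564 fell, of 18791 tested. Transcripts of plk2.L, a polo-like kinase, were 62.1-fold higher, at 9.54 ± 4.84 CPM in genistein against 0.150 ± 0.0905 in control (SD, n = 3 each; log2 fold change 5.96 ± 0.58 SE, edgeR quasi-likelihood adjusted p = 0.00103). This control mean lies under the limit of 0.203 to 0.228 CPM for 0 counts in a single control library. The size of the fold is therefore imprecise. Both homeologs of the apelin receptor rose, aplnr.S by 5.43 ± 0.91 and aplnr.L by 3.04 ± 0.58 on the log2 scale (edgeR adjusted p = 0.0112 and 0.0185). So did ccng1.L, which encodes cyclin G1 (3.63 ± 0.81), tent5a.L, a poly(A) polymerase family gene (3.40 ± 0.51), and pdk4.S, a kinase that restrains pyruvate dehydrogenase (3.23 ± 0.43), with edgeR adjusted p = 0.0352, 0.00698 and 0.00411.

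Among the genes with the largest falls, the homeobox gene dlx5.S, expressed in ectoderm, had 0 counts over the 3 genistein libraries against 87 in control (2.11 ± 0.835 CPM), at least 25.5-fold lower by the floor of 3 counts over the group (edgeR adjusted p = 0.0085). Likewise xmc.L had 0 against 41 counts, which fell by at least 3.59 on the log2 scale by the same floor (edgeR adjusted p = 0.0422). Transcripts of lpar6.L, a receptor for lysophosphatidic acid, fell by 3.62 ± 0.85 and those of lhx5.S, a LIM homeobox gene of the anterior neural plate, fell by 3.02 ± 0.59 on the log2 scale (edgeR adjusted p = 0.0428 and 0.0201).

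Among the genes of the Wnt lists, those past the test in genistein had fallen. Among 43 tested genes for pathway components, 5 fell and none rose: fzd7.S, a Wnt receptor, by -1.20 ± 0.17 (log2 ± SE), its homeolog fzd7.L by -0.60, the co-receptor lrp5.L by -0.86 ± 0.12, pygo2.S by -0.70 and tcf7l1.L by -0.60. Their edgeR adjusted p-values were 0.00509, 0.0128, 0.00551, 0.0294 and 0.0239, and adjusted over the list alone 11 fell. Of 21 zygotic Wnt targets, 2 fell and none rose (4 fell adjusted over the list alone). One was znrf3.S, a feedback inhibitor of the pathway, at -1.50 ± 0.36 (edgeR adjusted p = 0.0463). The other was hoxd1.L, with 1 count against 26, a ratio of control to genistein of 20.9 with an exact 95% interval of 3.44 to 858 from counting alone (edgeR adjusted p = 0.0441). The gene set test camera with a preset correlation placed both lists below other genes (adjusted p = 6.2e-05 for the components and 0.00282 for the zygotic targets), and with an estimated correlation both calls were lost (camera adjusted p = 0.63 and 0.262). Genes named beyond the fixed rule, here and further on, complete a count of 5 or fewer and were chosen after their values were seen.

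None of the 8 early Wnt dorsal targets, genes switched on by maternal beta-catenin on the dorsal side, passed the test in genistein, also when adjusted over the list alone. The list was not called by camera (adjusted p = 0.849, estimated correlation p = 0.981), where the median log2 value was 0.09 and the test pointed down. With library totals only as the scaling the list's median was -0.04, and without control 1, genistein 1 and genistein 3, where genistein 2 stands alone in its group, it was -0.76 with 8 of 8 values negative. The siamois gene sia1.L stood at -0.03 ± 0.35, sia2.S at -0.45 ± 0.40, nodal3.1.L at -0.64 ± 0.49 and nodal3.2.L at -1.54 ± 0.51 (log2 ± SE, none past the edgeR test). All siamois and nodal3 values were thus negative. Positive values in the list included nodal5.L (1.11 ± 0.56), nodal6.L (0.76 ± 0.60) and nodal6.S (0.21 ± 0.37), named after their values were seen. The median near 0 therefore joins members of opposite sign. Of 23 organizer genes none passed either, adjusted over the list alone included, with 17 of 23 values negative and a median of -0.65 (camera adjusted p = 0.0314, and 0.732 with an estimated correlation). Without those 3 libraries 22 of 24 values were negative with a median of -1.46. The 4-group fit put gsc.L at 1.76 ± 0.62, gsc.S at -0.40 ± 0.60, chrd.1.L at -1.68 ± 0.82, chrd.1.S at 0.38 ± 0.92 and chrd.2.L at -1.52 ± 0.96. The zygotic targets sp5.L and sp5.S stood at -0.34 ± 0.55 and -0.68 ± 1.25, and wnt8a.L and wnt8a.S at 0.80 ± 0.62 and 1.23 ± 0.71. The 8 copies of the ventral genes ventx1 and ventx2 lay between 0.00 and 1.57, none past the test. Without the same 3 libraries 7 of the 8 had negative values (-0.76 for ventx1.S to -0.17 for ventx1.2.S), and wnt8a.L and wnt8a.S stood at -0.43 and -1.50. In the fit with the covariate 2 early dorsal genes fell, nodal3.2.L (-1.73) and nodal3.1.L (-0.90), and 7 organizer genes (edgeR adjusted p = 7.03e-04 and 0.0475 for the former pair).

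Of 32 genes in the FGF and MAPK list, which holds FGF ligands and receptors beside targets, 5 fell and none rose (8 fell adjusted over the list alone). They were spry1.S and spry1.L, feedback inhibitors of receptor tyrosine kinases (-1.68 ± 0.24 and -1.34), fgfr4.S (-0.89 ± 0.16), the phosphatase gene dusp1.S (-0.82) and fos.S (-1.28), with edgeR adjusted p between 0.00515 and 0.0428. The list lay below other genes (camera adjusted p = 5.57e-05, and 0.262 with an estimated correlation). Of 30 neural ectoderm genes, 3 fell and none rose (4 adjusted over the list alone). Among these was zic1.S (-1.93 ± 0.42, edgeR adjusted p = 0.0331). The neural list had camera adjusted p = 0.00282, and 0.262 with an estimated correlation. In the epidermis list 4 of 27 fell and none rose: dlx5.S, tfap2c.L, which encodes an AP-2 factor (-1.81 ± 0.17), and the splicing regulators esrp1.S (-1.11 ± 0.15) and esrp1.L (-0.81). Adjusted over the list alone, 1 epidermal gene rose and 6 fell. The list's median was 0.08, its mean -0.36 and its test pointed down (camera adjusted p = 0.0868, 0.63 with an estimated correlation), and its median was -0.04 with library totals only. In the BMP and ventral list 3 of 32 fell, the inhibitory smad6.L (-0.97 ± 0.17) and smad6.S (-0.69) and the BMP antagonist szl.S (-1.28 ± 0.26), and none rose (4 fell adjusted over the list alone). Here the median was 0.25 while the test pointed down (camera adjusted p = 0.997, 0.999 with an estimated correlation).

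Among 70 cell cycle genes, 4 fell and none rose (9 fell adjusted over the list alone): the mitotic kinases aurkb.L (-1.26 ± 0.14, edgeR adjusted p = 0.00213), aurka.S, cdk1.L (-1.09 ± 0.16) and cdk1.S (-1.02). The list as a whole was not called (camera adjusted p = 0.109, 0.63 with an estimated correlation). In the p53 and stress list of 36 genes 1 rose and 1 fell, the latter chac1.S, a glutathione-degrading enzyme of the stress response, by -1.21 ± 0.23 (edgeR adjusted p = 0.0193). Adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.1, 0.723 with an estimated correlation). Of 39 maternal and germ plasm genes, mos.L (-0.58 ± 0.12) and bmp15.L (-1.06 ± 0.19) fell (edgeR adjusted p = 0.0231 and 0.0144), and adjusted over the list alone 3 rose and 3 fell. The list as a whole lay above other genes, with 30 of 39 values positive and a median of 0.25 (camera adjusted p = 0.0256, 0.732 with an estimated correlation). None of 27 mesendoderm and Nodal genes passed, adjusted over the list alone included (median 0.43, camera adjusted p = 0.0943, 0.732 with an estimated correlation). Both medians turned without control 1, genistein 1 and genistein 3, to -0.11 for the maternal list (26 of 39 values negative) and -0.36 for the mesendoderm list (9 of 27 positive), while the covariate fit put them at 0.18 and 0.26.

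Among lists chosen for known actions of isoflavones, both copies of arnt, the partner of the aryl hydrocarbon receptor, fell (arnt.S by 0.92 ± 0.14 and arnt.L by 0.74 ± 0.15; edgeR adjusted p = 0.00702 and 0.0254). The other 5 of the 7 genes in that list did not pass (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0668, 0.262 with an estimated correlation). The transporter gene abcc1.L was the only one of 14 NRF2 targets past the test (-0.92 ± 0.20, edgeR adjusted p = 0.0298; 1 fell adjusted over the list alone; camera adjusted p = 0.585, 0.732 with an estimated correlation). None of 12 estrogen response genes passed over all genes, and 3 fell adjusted over the list alone (median -0.02, mean -0.43; camera adjusted p = 0.585, 0.732 with an estimated correlation). No ribosomal protein gene passed, although 117 of 139 values were positive with a median of 0.33 (camera adjusted p = 0.00282, 0.732 with an estimated correlation). The 12 mitochondrially encoded genes all had positive values, median 0.46, and none passed (camera adjusted p = 0.145, 0.732 with an estimated correlation). The covariate fit put the median of the ribosomal list at 0.12.

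**Figure D2:**
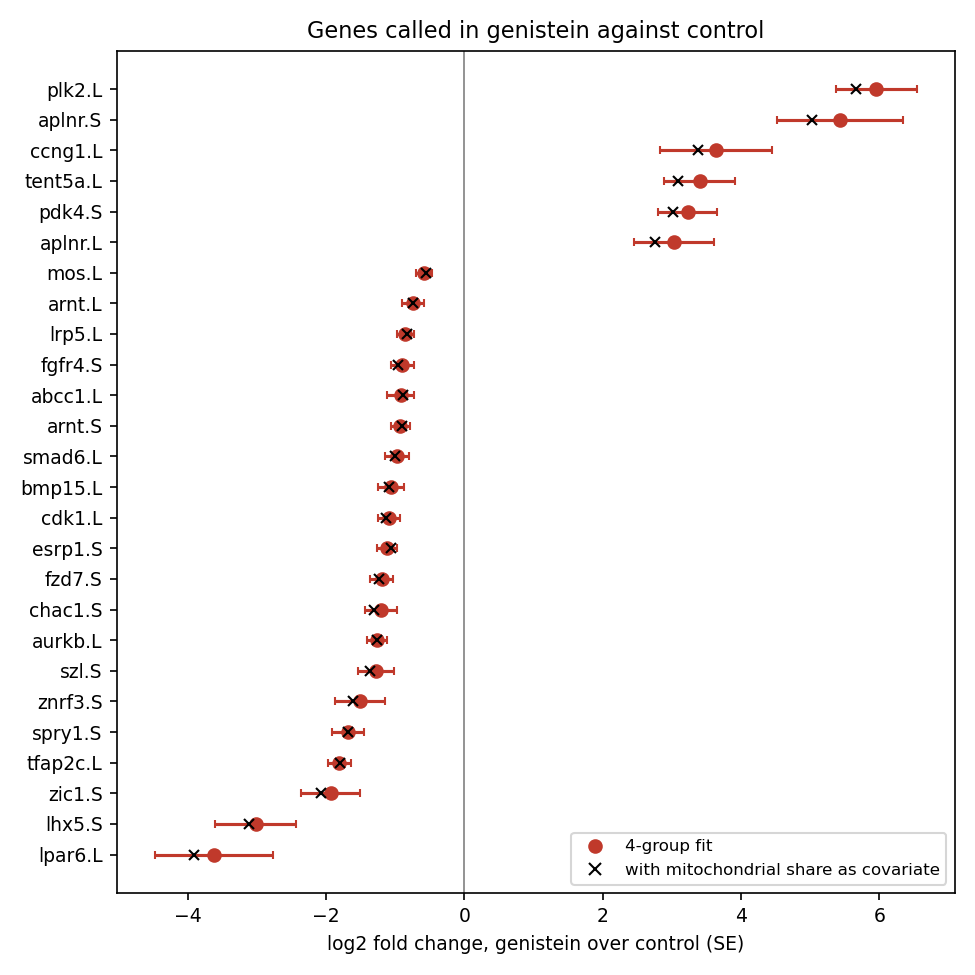
Log2 fold change in genistein against control (horizontal axis) of 26 of the 32 named genes that passed the test, those with over 3 counts in each group whose values are reported; dots with bars are the value ± SE from the 4-group fit, and crosses the value with the mitochondrial share as covariate. Values run from 5.96 for plk2.L to -3.62 for lpar6.L.

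The counts depended on the libraries in the fit. With the mitochondrial share as covariate 1612 genes rose and 2042 fell, the 632 called genes among them, and without the 3 libraries that stood apart 339 rose and 970 fell, with 24 of the 68 higher and 418 of the 564 lower genes kept. Leaving out 1 library at a time from the covariate fit gave 451 (without control 1) to 2369 (without genistein 2) higher and 1204 to 2223 lower, without the same libraries. The called total of 632 was 1065 without control 1, 195 without control 2, 220 without control 3, 319 without genistein 1, 4757 without genistein 2 and 181 without genistein 3. It was 393 and 412 without BIO 1 and BIO 3, 403 and 375 without Chiron 2 and Chiron 3, and within 1.5 times of 632 without BIO 2 or Chiron 1. With only the 6 genistein and control libraries in the fit, 1 gene was called, ets2.L, at -1.90 on the log2 scale, a gene chosen after its value was seen. The 4-group fit gives each gene 1 spread for all groups. Chi-square per degree of freedom between replicates was 27.5 to 177 in control and 21.8 to 200 in genistein. It was 3.28 to 23.6 in BIO and 2.28 to 7.73 in Chiron. The 632 calls thus rest on a spread shared with those evener groups. Of the 32 named genes past the test all 32 kept their direction without any 1 library, and 12 kept the call in all 12 such fits: plk2.L, tent5a.L, pdk4.S, dlx5.S, fzd7.S, lrp5.L, tfap2c.L, esrp1.S, spry1.S, aurkb.L, cdk1.L and arnt.S. The genes ccng1.L (3.12 to 5.68 across these fits), lpar6.L (-5.18 to -2.91), znrf3.S and hoxd1.L kept it in 2 of the 12. It was kept in 11 by aplnr.S (4.79 to 6.88) and in 8 by aplnr.L (2.71 to 3.83). Of the 32, 28 passed without control 1, 21 without control 2, 17 without control 3, 19 without genistein 1, 32 without genistein 2 and 15 without genistein 3. The number was 25, 28 and 25 without BIO 1, 2 and 3, and 26, 26 and 25 without Chiron 1, 2 and 3. Without genistein 2 its group holds only genistein 1 and genistein 3, which are among the libraries that stood apart. Counts from that fit are therefore no check of the treatment alone. DESeq2 called 642 genes higher and 1058 lower, and with counts of homeologs summed 34 and 356 were called.

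In BIO against control 3 genes rose and 2 fell. The siamois gene sia1.L, a direct target of dorsal Wnt signalling, was at 52.8 ± 5.04 CPM in BIO against 8.80 ± 3.42 in control (SD, n = 3 each; log2 fold change 2.59 ± 0.35 SE, edgeR adjusted p = 0.0477). The other risers were foxf1.L, a forkhead gene of ventrolateral mesoderm (3.72 ± 0.43, edgeR adjusted p = 0.0435), and the ectodermal AP-2 gene tfap2a.L (2.88 ± 0.35, edgeR adjusted p = 0.0435). Transcripts of the polo-like kinase gene plk3.S fell by 0.66 ± 0.09 (edgeR adjusted p = 0.0477), and the other falling gene carried an identifier only. Other dorsal genes had positive values that did not pass: nodal3.1.L 2.36 ± 0.47, nodal3.2.L 1.61 ± 0.46, sia2.S 1.26 ± 0.38, gsc.L 3.05 ± 0.56, gsc.S 1.03 ± 0.54, chrd.1.L 1.43 ± 0.63, chrd.1.S 2.29 ± 0.83 and chrd.2.L 0.95 ± 0.72. Values of sp5.L and sp5.S were 2.34 ± 0.49 and 2.21 ± 0.91, the ventx copies lay between 1.40 and 2.55, and wnt8a.L and wnt8a.S stood at 0.13 ± 0.62 and 0.93 ± 0.71.

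All 8 early dorsal targets had positive values in BIO, with 1 past the test (sia1.L), 5 adjusted over the list alone and a median of 1.24 (camera adjusted p = 6.75e-14, 0.137 with an estimated correlation). Of 27 mesendoderm and Nodal genes 26 were positive and none passed, with 16 higher adjusted over the list alone and a median of 1.46 (camera adjusted p = 8e-28, 0.137 with an estimated correlation). Of 23 organizer genes 20 were positive, none passed and 1 was higher adjusted over the list alone (camera adjusted p = 1.35e-11, 0.355 with an estimated correlation). The BMP and ventral list had no gene past the test and 10 higher adjusted over the list alone (median 0.18; camera adjusted p = 1.59e-05, 0.515 with an estimated correlation). In the epidermis list 1 of 27 rose, tfap2a.L, and 4 were higher adjusted over the list alone. There the median was -0.08, the mean 0.18 and the test pointed up (camera adjusted p = 0.0232, 0.409 with an estimated correlation). Lists that lay below other genes were the maternal one (31 of 39 negative, camera adjusted p = 4.48e-06, estimated 0.409), the ribosomal one (136 of 139 negative, 1.35e-11, estimated 0.548) and the mitochondrial one (12 of 12 negative, 4.74e-09, estimated 0.355). No member of these 3 passed over all genes, and 9 mitochondrial genes were lower adjusted over the list alone. In BIO the mitochondrial share averaged 1.35%, against 6.24% in control. No other list was called by camera in BIO.

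With the mitochondrial share as covariate 123 genes rose and 61 fell in BIO, and without the 3 libraries that stood apart 131 rose and 74 fell. Leaving out 1 library from the covariate fit gave 34 (without control 2) to 141 (without Chiron 1) higher and 9 (without control 2) to 84 (without genistein 2) lower. In the covariate fit 7 of the 8 early dorsal genes passed, among them nodal3.1.L (3.06, edgeR adjusted p = 1.73e-04), with 7 organizer, 12 BMP and ventral and 17 mesendoderm genes. There the early dorsal, organizer and mesendoderm calls held with an estimated correlation (camera adjusted p = 0.00303, 0.0352 and 0.0171), and the maternal, ribosomal and mitochondrial medians were 0.01, 0.20 and -0.14. In the 4-group fit the count of 5 genes was 0 without control 2, control 3, BIO 1, BIO 2, BIO 3, Chiron 2 or Chiron 3. It was 1 without genistein 3 or Chiron 1, 2 without genistein 1 and 28 without genistein 2. None of the 4 named genes passed in all 12 of these fits, though all 4 kept their direction. DESeq2 called 44 genes higher and 71 lower, and with only the 6 BIO and control libraries in the fit none was called by edgeR (1275 genes at an unadjusted p under 0.05).

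No gene passed the edgeR test in Chiron against control, where the smallest adjusted p was 0.0874. An unadjusted p under 0.05 was found for 1131 genes (6.02%), where unchanged genes would give 5%. DESeq2 called 31 higher and 24 lower, and limma-voom 6 higher and 1 lower. The 10 symbols with the smallest p, none of which passed, included the ectodermal genes tfap2a.L (2.76 ± 0.35), tfap2a.S (2.39 ± 0.34), grhl3.L (2.47 ± 0.36) and grhl3.S (2.70 ± 0.50). They also held sia1.L at 2.33 ± 0.34 (44.2 ± 9.16 CPM against 8.80 ± 3.42), lhx5.L (2.23 ± 0.37), sp5l.L (2.28 ± 0.42), dusp5.L (1.60 ± 0.30), the endodermal gene sox17b.1.S (1.12 ± 0.21) and plk3.S (-0.52 ± 0.09). Dorsal genes had values of 2.35 ± 0.47 for nodal3.1.L, 1.87 ± 0.46 for nodal3.2.L, 1.51 ± 0.38 for sia2.S, 2.59 ± 0.62 for chrd.1.L, 2.83 ± 0.82 for chrd.1.S and 2.60 ± 0.67 for chrd.2.L. Values were 1.55 ± 0.61 for gsc.L, 0.05 ± 0.56 for gsc.S, 1.34 ± 0.49 for sp5.L, 2.17 ± 0.91 for sp5.S, 0.02 ± 0.62 for wnt8a.L and 0.26 ± 0.74 for wnt8a.S. The ventx copies lay between 0.41 and 1.35.

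By list, 7 of 8 early dorsal genes had positive values in Chiron, 5 were higher adjusted over the list alone, and the median was 1.51 (camera adjusted p = 3.38e-12, 0.373 with an estimated correlation). Positive values were found for 24 of 27 mesendoderm genes (camera adjusted p = 5.52e-09) and 19 of 23 organizer genes (2.23e-07), with 2 and 3 genes higher adjusted over the list alone; with an estimated correlation the camera adjusted p was 0.384 for both. The neural list (23 of 30 positive, median 0.12, camera adjusted p = 0.00151) and the epidermis list (median -0.04, mean 0.22, test up, 0.0342) were also called, and 4 epidermal genes were higher adjusted over the list alone. Below other genes lay the maternal list (32 of 39 negative, camera adjusted p = 9.8e-06), the ribosomal list (138 of 139 negative, median -0.62, 1.35e-22) and the mitochondrial list (11 of 12 negative, median -2.37, 2.27e-06). With an estimated correlation each of these 5 calls had camera adjusted p = 0.384. The mitochondrial share averaged 1.34% in Chiron and 6.24% in control. No other list was called.

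With the mitochondrial share as covariate 94 genes rose and 23 fell in Chiron, and without the 3 libraries that stood apart 119 rose and 27 fell. The covariate fit with 1 library left out gave 24 (without control 2) to 138 (without BIO 2) higher and 2 (without control 3) to 39 (without genistein 2) lower. In the covariate fit 6 early dorsal, 5 organizer, 6 BMP and ventral, 5 epidermal and 2 of 27 mesendoderm genes passed. The early dorsal call held with an estimated correlation (camera adjusted p = 0.00292), and the organizer and mesendoderm calls did not (0.0631 for both). The count of 0 in the 4-group fit was 7 without control 1 and 14 without genistein 2.

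**Figure D3:**
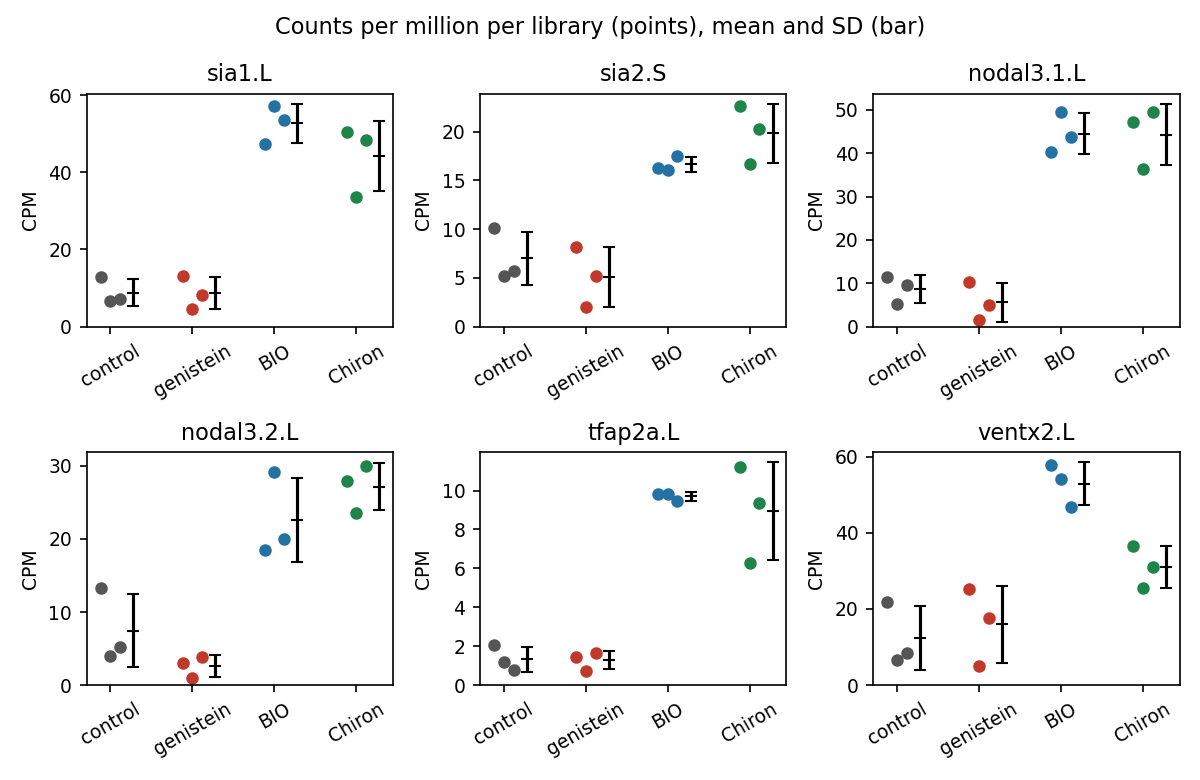
CPM (vertical axes) of sia1.L, sia2.S, nodal3.1.L, nodal3.2.L, tfap2a.L and ventx2.L in the 4 groups; each dot is 1 library, and the bar beside the dots is the mean and SD of 3. For sia1.L the means are 8.80 in control, 8.63 in genistein, 52.8 in BIO and 44.2 in Chiron.

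Between BIO and Chiron no gene passed the edgeR test, where 217 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.204; limma-voom called none and DESeq2 2 lower in BIO. This does not show that the compounds act alike. Among the 10 symbols with the smallest p, none past the test, higher values in BIO were those of foxf1.L (1.74 ± 0.35), prph.L (2.42 ± 0.63), gata2.L (2.23 ± 0.60), cass4.L (2.03 ± 0.61) and nodal1.L (1.13 ± 0.34). Lower values in BIO were those of angpt4.L (-1.97 ± 0.48), ugdhl.L (-2.67 ± 0.68), sgms2.L (-1.63 ± 0.47), dusp1.S (-0.76 ± 0.19) and il1rapl2.L (-0.80 ± 0.24). As a group mesendoderm genes stood higher in BIO than in Chiron (25 of 27 positive, median 0.65, camera adjusted p = 5.45e-18, 0.43 with an estimated correlation), as did BMP and ventral genes (27 of 32, median 0.27, camera adjusted p = 7.61e-13, estimated 0.477). Organizer genes (camera adjusted p = 0.0366, estimated 0.987) and ribosomal protein genes (3.64e-07, estimated 0.987) were also placed higher in BIO, and neural genes lower (0.00672, estimated 0.477). The count of 0 was 1 gene lower in BIO without genistein 2 and with the covariate, and 2 without the 3 libraries that stood apart.

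Genistein was also set directly against the Wnt activators. Against BIO 130 genes were higher and 553 lower in genistein, and against Chiron 34 and 407. All 4 of the siamois and nodal3 genes that fell against BIO also fell against Chiron: sia1.L by -2.61 and -2.36, sia2.S by -1.71 and -1.96, nodal3.1.L by -3.00 and -3.00, and nodal3.2.L by -3.15 and -3.41 (log2; edgeR adjusted p between 0.00644 and 0.0438 against BIO, 0.0076 and 0.0297 against Chiron). Higher in genistein than in BIO and Chiron were aplnr.S (4.62 ± 0.83 and 4.58 ± 0.83), plk2.L (3.89 ± 0.47 and 4.18 ± 0.48), tent5a.L (3.15 ± 0.50 and 2.85 ± 0.48) and the Notch ligand gene dll1.L, at 15.4 ± 9.29 CPM against 1.37 ± 0.583 and 1.66 ± 0.732, with edgeR adjusted p between 0.00379 and 0.0186. With 0 counts in genistein, dlx5.S was at least 53.1-fold lower than in BIO and 53.5-fold lower than in Chiron, and xmc.L at least 26.4-fold and 80.6-fold lower. The 1 count of hoxd1.L stood against 94 in BIO and 87 in Chiron, ratios of 71.8 (exact 95% interval 12.6 to 2865) and 62.9 (11 to 2512). Transcripts of lhx5.S fell by 4.51 ± 0.55 relative to BIO and those of lpar6.L fell by 4.47 ± 0.81 relative to Chiron (edgeR adjusted p = 0.005 and 0.0188). Of the 8 named genes past the test by the rule in each contrast, plk2.L, dlx5.S, hoxd1.L and lhx5.S kept the call in all 12 fits without 1 library against BIO, and plk2.L, dlx5.S, hoxd1.L and xmc.L against Chiron. Against both compounds aplnr.S and dll1.L kept it in 7 of the 12, and 5 of the 8 kept it without control 1, genistein 1 and genistein 3.

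Early dorsal genes as a list lay lower in genistein than in BIO (median -1.36, 4 of 8 fell, 5 adjusted over the list alone, camera adjusted p = 6e-06) and than in Chiron (median -1.63, 4 fell, 5 adjusted over the list alone, 2.51e-05). The estimated correlation gave camera adjusted p = 0.272 and 0.399. Organizer genes had 4 and 3 members lower (15 and 9 adjusted over the list alone) and medians of -1.76 and -1.44 (camera adjusted p = 4.52e-09 and 1.3e-06, estimated 0.272 and 0.399). FGF and MAPK targets had 5 and 5 lower (camera adjusted p = 3.75e-05 and 2.41e-06, estimated 0.261 and 0.156), and neural genes 5 and 5 (2.24e-04 and 4.46e-06, estimated 0.261 and 0.156). Zygotic Wnt targets had 4 and 2 lower (3.91e-04 and 6.37e-04, estimated 0.261 and 0.271), Wnt pathway components 5 and 4 (1.95e-06 and 5.61e-06, estimated 0.272 and 0.399) and epidermal genes 7 and 6 (0.00204 and 0.00297, estimated 0.272 and 0.383). Against Chiron the epidermal median was 0.13 and the mean -0.58, and the median was -0.04 with library totals only. Mesendoderm genes were placed lower against BIO (3 fell, camera adjusted p = 1.28e-06, estimated 0.272) and not called against Chiron (camera adjusted p = 0.0646, estimated 0.588). The BMP and ventral list was placed lower against BIO (median -0.54, none past the test, camera adjusted p = 0.00685, estimated 0.504) and not called against Chiron (0.836, estimated 0.958). Maternal genes (1.28e-06 and 2.41e-06, estimated 0.272 and 0.399), ribosomal protein genes (2.96e-11 and 8.08e-18, estimated 0.448 and 0.416) and mitochondrially encoded genes (2.39e-06 and 3.11e-05, estimated 0.272 and 0.399) lay higher in genistein, whose mitochondrial share averaged 7.96% against 1.35% and 1.34%. The p53 and stress list lay higher against BIO only by the preset correlation (2 rose and 1 fell, camera adjusted p = 0.0367, estimated 0.409) and was not called against Chiron (0.0724, estimated 0.444).

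In the covariate fit 56 genes were higher and 653 lower in genistein than in BIO, with 32 of the 130 higher and 386 of the 553 lower genes kept, and 31 and 665 against Chiron, with 16 of 34 and 371 of 407 kept. Without the 3 libraries that stood apart 14 of the 130 and 291 of the 553 kept the call against BIO, and 6 of 34 and 232 of 407 against Chiron. Leaving out 1 library from it gave 17 (without BIO 2) to 301 (without genistein 2) higher and 385 (without BIO 3) to 709 (without Chiron 1) lower than in BIO. Against Chiron the same gave 5 to 1084 higher and 364 to 907 lower, the lowest without Chiron 3 and the highest without genistein 2. In the covariate fit the early dorsal, organizer, zygotic Wnt, epidermal and FGF and MAPK calls held with an estimated correlation against BIO (camera adjusted p = 0.00824, 0.0212, 0.0162, 0.0212 and 0.0212). The same 5 held against Chiron (camera adjusted p = 0.0152, 0.0342, 0.0212, 0.0328 and 0.0212), as did the neural list (0.0439), and no other list was called there with an estimated correlation. Scaling by library totals only moved the median of all genes from -0.02 to -0.18 against BIO, from -0.03 to -0.19 against Chiron and from 0.03 to -0.09 in genistein against control; 70 genes were then higher and 937 lower than in BIO, and 28 and 665 in place of 34 and 407 against Chiron. With only the 6 libraries compared in the fit, 0 genes were called against BIO by edgeR (4489 at an unadjusted p under 0.05) and 17 against Chiron, while DESeq2 on all 12 libraries turned the balance, with 2366 higher and 1514 lower against BIO and 2590 and 1348 against Chiron. Against BIO the 683 genes were 2716 without control 1, 298 without control 3, 161 without genistein 1, 8811 without genistein 2, 90 without genistein 3, 119 without BIO 1, 299 without BIO 2, 48 without BIO 3, 403 without Chiron 1, 317 without Chiron 2 and 266 without Chiron 3. Against Chiron the 441 genes were 2786 without control 1, 251 without control 3, 161 without genistein 1, 9125 without genistein 2, 138 without genistein 3, 220 without BIO 1, 267 without BIO 3, 107 without Chiron 1, 201 without Chiron 2 and 112 without Chiron 3. In edgeR the balance also turned without genistein 2, with 4549 higher and 4262 lower against BIO and 4651 and 4474 against Chiron. Genistein 1 and genistein 3 then remain, with mitochondrial shares of 14.1% and 8.37% against at most 2.66% in BIO and Chiron. The share is then confounded with treatment, and these counts do not measure the treatment alone. Without control 1 the balance turned against Chiron (1500 and 1286) and not against BIO (1329 and 1387).

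**Figure D4:**
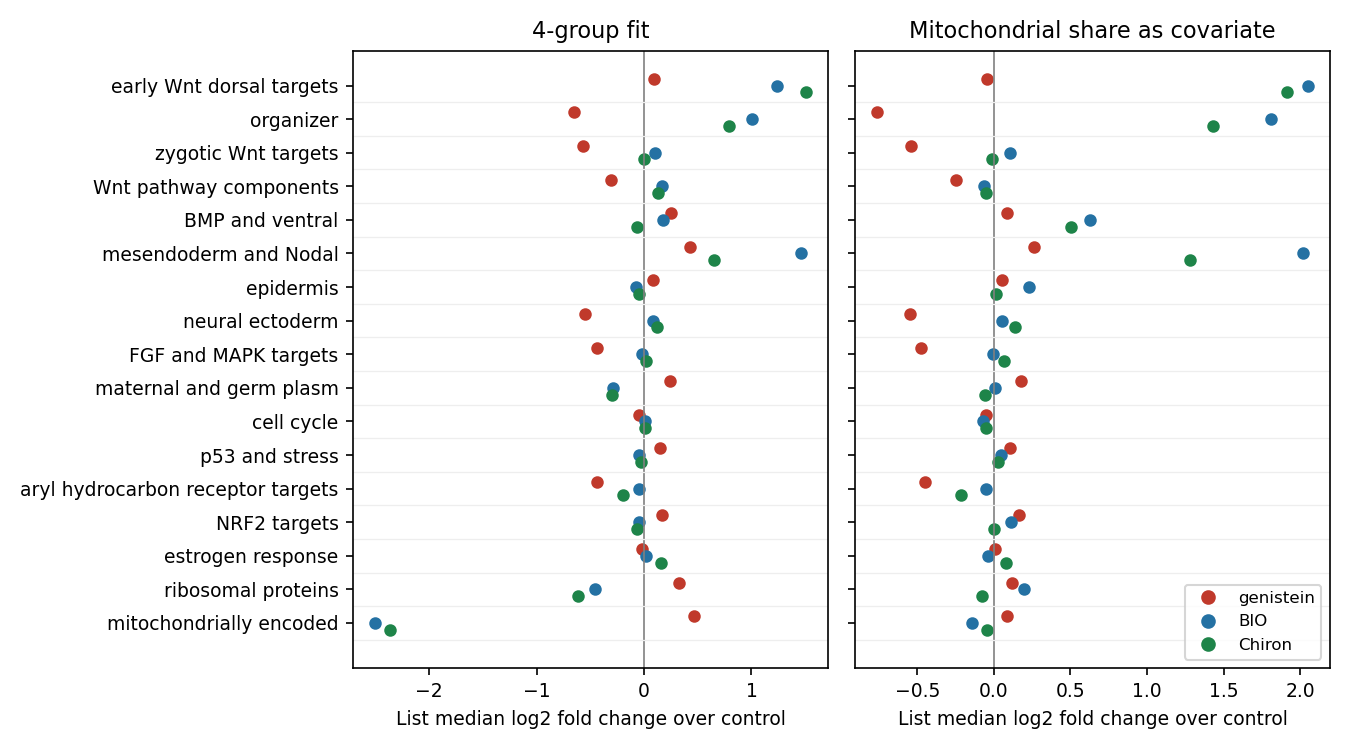
Median log2 fold change over control (horizontal axes, which differ in range) of the 17 gene lists for genistein, BIO and Chiron, in the 4-group fit (left) and with the mitochondrial share as covariate (right). The early dorsal median is 0.09 in genistein, 1.24 in BIO and 1.51 in Chiron on the left, and -0.04, 2.05 and 1.91 on the right.

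Fold changes over control correlated at r = 0.85 between BIO and Chiron over 18791 genes, which are not independent replicates, where unchanged groups sharing the same 3 controls gave 0.50 in 10 simulations. The covariance was 0.158 against a simulated 0.0525, a difference of 0.105. The simulations gave each gene the same spread in every group and drew genes independently. In the data the shared controls were more uneven, with an SD of the mitochondrial share of 6.54 against 1.14 in BIO and 0.313 in Chiron. The simulated r and covariance may therefore be too low for unchanged groups of such libraries, and these differences do not measure a shared response. Between genistein and BIO r was -0.06 (simulated 0.49; covariance -0.0132 against 0.0515), and between genistein and Chiron -0.12 (simulated 0.50; covariance -0.0273 against 0.0522). With the covariate the values were 0.19 and 0.13, under the simulated 0.33 and 0.36, with covariances of 0.0346 against 0.0193 and 0.0207 against 0.0201; between BIO and Chiron r was then 0.77 against 0.60. No simulation was run without the 3 libraries that stood apart, where r was 0.11 for both pairs with genistein. No gene was called in BIO and Chiron together in the 4-group fit, and 2 fell in genistein and BIO alike, plk3.S and a gene with an identifier only, where independent lists would share 0.06. Under the covariate fit 68 genes rose and 20 fell in BIO and Chiron alike, where independent lists would share 0.615 and 0.0747 and the simulated number was 0. In that fit 16 genes rose and 47 fell in genistein and BIO alike (10.6 and 6.63 from independent lists), and 6 rose and 20 fell in genistein and Chiron (8.06 and 2.5). There 26 genes fell in genistein and rose in Chiron (10.2 from independent lists) and 18 fell in genistein and rose in BIO (13.4). The 3 controls cannot be split into parts of 2 libraries each, so part of any excess in r or in genes moved alike may come from the shared controls.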

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

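All 6 comparisons kept a count within 1.5 times of the reported one, in each direction, with RLE size factors, no count filter, and at least 1 CPM in 3 libraries; the fits with the mitochondrial share as covariate and without control 1, genistein 1 and genistein 3 were chosen only after the results were seen. For values that moved, the cause was not tested unless the setting itself names it, such as a fold minimum. Across the alternatives single named genes kept direction and side of the threshold in 2500 cases, lost the call in 250, gained it in 120 and turned sign in 42. Set tests did so in 109, 30, 6 and 8 cases. Counts of list members have no sign to turn and were judged by size alone. They stayed within 1.5 times in 2174 cases, counts of 0 that stayed 0 included. In 97 cases they were smaller by more than that, and in 177 larger or raised from 0. The 2500 cases include those where DESeq2 gave no adjusted p. Among them were 3 of the 32 named genes called in genistein against control, which DESeq2 thus did not call. With RLE size factors the value of wnt8a.L in Chiron was -0.00133, and the 3 correlations kept their signs in that fit. With the mitochondrial share as covariate, genistein with BIO had r = 0.19 and genistein with Chiron 0.13, against -0.06 and -0.12, where simulated unchanged groups gave 0.33 and 0.36 in that fit.

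The replicate numbers showed no consistent pairing: of 18 same-number pairs, 5 had correlated deviations over 0.1, the values ran from -0.55 to 0.77, and 5 of the 12 libraries correlated best with their own number. The highest values were those of control 2 with genistein 2 (0.77) and control 1 with genistein 1 (0.68). The uneven mitochondrial share enters these correlations and the labels do not say what the numbers mark. Whether samples were paired is therefore not decided. With the number as a replicate block 400 genes were called in genistein against control in place of 632, 19 of them higher. The lower count in BIO was 1. Genistein against BIO gave 22 higher and 318 lower (340 in all), and genistein against Chiron 17 and 251 (268). In genistein and BIO alike 1 gene was called, and the BMP and ventral list had a camera adjusted p of 0.918 in genistein, with its direction turned. The mesendoderm list, not called without the block, had a camera adjusted p of 0.0177 in genistein against control and 0.0336 against Chiron with it, and no other set call changed. An estimated correlation was not run with the block, and without the block its camera adjusted p was 0.732 and 0.588. The block moved no other count of calls by over 1.5 times.

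DESeq2 called 642 genes higher and 1058 lower in genistein, 44 and 71 in BIO, 31 and 24 in Chiron, 2 lower in BIO than Chiron, 2366 and 1514 in genistein against BIO, and 2590 and 1348 against Chiron. It called 45 genes in genistein and BIO alike, 19 in genistein and Chiron and 30 in BIO and Chiron, and wnt8a.L in Chiron was at -0.0139. With limma-voom 6 genes were higher and 1 lower in Chiron, 83 were higher in genistein than BIO, 1 was called in genistein and Chiron alike and 3 in BIO and Chiron, and chrd.1.S in genistein was at -0.53. Library totals only gave 18 higher in genistein, 0 lower in BIO, 6 higher in Chiron, 70 higher and 937 lower in genistein against BIO, 665 lower against Chiron, 0 alike in genistein and BIO, 2 alike in BIO and Chiron, and -0.11 for ventx1.S in genistein. With an absolute log2 fold change of at least 1, genistein had 12 higher and 180 lower, BIO 1 lower, genistein against BIO 36 and 186, against Chiron 17 and 157, and 0 were alike in genistein and BIO. Summed homeologs gave 34 and 356 in genistein, 1 lower in BIO, 44 and 333 against BIO, 20 and 265 against Chiron, and 1 alike in genistein and BIO. With only the 6 libraries compared, edgeR called 0 higher and 1 lower in genistein (1726 at an unadjusted p under 0.05; DESeq2 on 12 libraries 642 and 1058), 0 and 0 in BIO (1275; DESeq2 44 and 71), 2 lower in BIO than Chiron, 0 and 0 in genistein against BIO (4489; DESeq2 2366 and 1514), and 0 higher and 17 lower against Chiron. In that fit 0 were alike in genistein and BIO, and ventx1.S in genistein was at -0.0221. Fewer libraries leave fewer degrees of freedom, and the spread then comes only from the groups compared. These causes of the changed counts were not separated.

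With the mitochondrial share as covariate 1612 genes were higher and 2042 lower in genistein, 123 and 61 in BIO, 94 and 23 in Chiron, 1 lower in BIO than Chiron, 56 higher in genistein than BIO and 665 lower than Chiron. In that fit 63 were alike in genistein and BIO, 26 in genistein and Chiron and 88 in BIO and Chiron, and ventx1.S in genistein was at -0.17. Its camera adjusted p, with the direction turned, was 0.0111 for Wnt pathway components in BIO and 0.0135 in Chiron, 0.129 and 0.0648 for p53 and stress, 0.367 and 0.564 for NRF2 targets, and 1.91e-05 for ribosomal proteins in BIO. With an estimated correlation the calls of that fit were lost, at camera adjusted p = 0.513 and 0.412 for Wnt pathway components in BIO and Chiron and 0.56 for ribosomal proteins in BIO. Without control 1, genistein 1 and genistein 3, where genistein 2 stands alone in its group, 339 were higher and 970 lower in genistein, 131 and 74 in BIO, 119 and 27 in Chiron, 2 lower in BIO than Chiron, and 18 higher in genistein than Chiron. Alike were 53 in genistein and BIO, 26 in genistein and Chiron and 89 in BIO and Chiron. Values in genistein were then -5.73 for chrd.1.S, -0.17 for ventx1.2.S, -0.69 for ventx1.L, -0.76 for ventx1.S, -0.20 for ventx2.2.L, -0.46 for ventx2.2.S, -0.57 for ventx2.L, -0.67 for ventx2.S, -0.43 for wnt8a.L and -1.50 for wnt8a.S.

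Leaving out each library in turn gave 5 to 2317 genes higher and 176 to 2440 lower in genistein, 0 to 14 higher and 0 to 14 lower in BIO, and 0 to 12 higher and 0 to 2 lower in Chiron. It gave 0 to 1 lower in BIO than Chiron, 1 to 4549 higher and 47 to 4262 lower in genistein than BIO, and 3 to 4651 higher and 104 to 4474 lower than Chiron. Alike were 0 to 9 in genistein and BIO, 0 to 2 in genistein and Chiron and 0 to 10 in BIO and Chiron. Each highest count came without genistein 2, where only genistein 1 and genistein 3, both high in mitochondrial share, remain in the group. The correlation ran from -0.24 to 0.16 for genistein with BIO, -0.31 to 0.10 for genistein with Chiron, and 0.79 to 0.90 for BIO with Chiron. The value of wnt8a.L in BIO ran from -0.21 to 0.92. In Chiron gsc.S ran from -0.28 to 0.83, wnt8a.L from -0.32 to 0.82 and wnt8a.S from -0.22 to 0.96. In genistein chrd.1.S ran from -0.70 to 1.5, gsc.S from -0.84 to 0.38, sia1.L from -0.45 to 0.33, sp5.L from -1.36 to 0.13, sp5.S from -5.08 to 0.083, ventx1.L from -0.033 to 1.17, ventx1.S from -0.43 to 0.72, ventx2.L from -0.12 to 1.08 and ventx2.S from -0.075 to 0.96. Values that kept their sign could move as well: in genistein chrd.1.L ran from -2.75 to -0.93 and chrd.2.L from -5.94 to -0.90. None of these values passed the test with all 12 libraries. Depth set the lower limit of 0.194 to 0.270 CPM per library and leaves genes of 1 to 3 counts, such as hoxd1.L, without a precise fold.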

Other observations

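Of the tests in this part, those of short genes, of mitochondrial RNA alone and of the splits without the covariate were set before their results were seen, and all others were chosen after; the genes named first were likewise chosen after their values were seen. In genistein against control the ETS factor gene ets2.L fell by 1.89 ± 0.14 on the log2 scale (SE), from 71.7 ± 5.71 CPM in control to 19.3 ± 0.412 (SD, n = 3 each; edgeR adjusted p = 2.86e-04). The Krüppel-like factor gene klf2.S fell by 1.51 ± 0.11, the kinase gene pim3.L by -1.36 ± 0.12, and nfkbia.S, which encodes an inhibitor of NF-kappaB, by -1.63 ± 0.20 (edgeR adjusted p = 2.86e-04, 6.96e-04 and 0.00303). The mitotic kinesin gene kif11.L, tacc3.S and ect2.S fell by 1.36 ± 0.15, -1.22 ± 0.14 and -1.06 ± 0.13 (edgeR adjusted p = 0.00224, 0.00273 and 0.0029). The Wnt feedback gene axin2l.L fell by 0.90 ± 0.12 and cyp26a1.S, which encodes an enzyme that degrades retinoic acid, fell by 2.78 ± 0.50 (edgeR adjusted p = 0.00411 and 0.0144). The polo-like kinase gene plk3.S fell in genistein (-1.02 ± 0.09) and BIO (-0.66 ± 0.09), with edgeR adjusted p = 6.96e-04 and 0.0477. In Chiron it stood at -0.52 ± 0.09 and fell with the covariate (edgeR adjusted p = 0.0122). With the covariate ets2.L also fell in BIO and Chiron (-0.86 and -0.59) and pim3.L in BIO (-0.62). There pdk4.S rose in BIO and Chiron (2.55 and 1.81) and cyp26a1.S rose in Chiron (1.44), with edgeR adjusted p between 0.00366 and 0.0451 for all of these. None of these changes passed in the 4-group fit. The genes klf2.S, nfkbia.S, kif11.L, tacc3.S, ect2.S and axin2l.L passed in BIO or Chiron in neither fit.

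Further genes rose in BIO and in Chiron in the covariate fit. Their values in BIO and Chiron were 2.79 and 2.89 for sp5l.L, 2.35 and 2.49 for admp.L, an organizer BMP ligand gene, and 2.06 and 2.36 for the hairy-related gene hes5.8.L. All 3 fell in genistein in that fit, by -1.47, -1.30 and -1.29 (edgeR adjusted p = 0.00536, 0.0113 and 7.86e-04). In the 4-group fit none of them passed in these comparisons. Without control 1, genistein 1 and genistein 3 all 3 passed in BIO and Chiron (edgeR adjusted p between 3.43e-04 and 0.0316), and sp5l.L in genistein (edgeR adjusted p = 0.0441). With the covariate the endodermal gene sox17b.1.L rose by 2.02 and 1.74 in BIO and Chiron, and id3.L, a BMP target, by 3.15 and 1.68 (edgeR adjusted p between 2.7e-04 and 0.0266). In the 4-group fit neither passed in BIO or Chiron (edgeR adjusted p between 0.176 and 0.645), and without the 3 libraries both did (between 1.64e-04 and 0.00758). With the covariate id3.L rose in genistein as well, by 1.03 (edgeR adjusted p = 0.0221), but did not pass there in the 4-group fit or without the 3 libraries (edgeR adjusted p = 0.194 and 0.131).

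The first pattern was the uneven mitochondrial share, on which 9933 genes (52.9%) had a within-group slope at an edgeR adjusted p under 0.05. With the mitochondrial genes left out, component 1 held 57.2% of the variance and the same 3 libraries were outermost. Only 12 of 18892 genes were left out, so component 1, at 57.4% with them, could hardly change. The result does show that nuclear genes carry the pattern, which argues against more mitochondrial RNA alone. Short genes over-represented in those libraries may account for part of it: Spearman's rho across 17394 nuclear genes of the slope with the length of the gene along the genome was -0.439, genes are not independent replicates, and that length is not transcript length. A difference in developmental stage stays open: 82.1% of maternal genes (32 of 39) and 85.2% of mesendoderm genes (23 of 27) had a positive slope, but after the trend with gene length was removed, a step and bound added after the first result, 68.4% and 65.4% did. No effect of treatment was tested for this pattern. It lay within groups and also between them, since the share averaged 6.24% in control and 7.96% in genistein against 1.35% in BIO and 1.34% in Chiron. The share is thus partly confounded with treatment where the covariate fit sets BIO or Chiron against control or genistein.

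The second pattern was the 564 genes lower in genistein. Whether the uneven share was the whole cause is not decided by the calls kept. With the covariate 100% of these genes (564 of 564) stayed called lower, but they were chosen as called without it. The covariate also lowered the spread, and the mean share differed little between control (6.24%) and genistein (7.96%), so few calls could be lost. Their median log2 value was -0.83 before and -0.80 after, so adjusting for the share did not remove the falls. Without the 3 libraries 564 had negative values, with a median of -0.83, but the remaining libraries had also served to choose the genes. Slower development of the genistein embryos stays open, since 33.3% of mesendoderm genes (9 of 27) were positive without the 3 libraries, where genistein 2 stands alone, and 66.7% (18 of 27) with the covariate. An effect of genistein itself, which the design names, stays open as well.

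The third pattern was the small number of genes called in BIO and Chiron. Spread added by the uneven libraries is consistent with the 184 genes called in BIO with the covariate and 205 without the 3 libraries, 141 of them in both, and with 117 and 146 in Chiron, 89 in both. In simulated data 2-fold changes in BIO were recovered at 46% without the covariate and 81% with it, with 9 and 22 false calls. Each set of simulated data was drawn with the spread of its own fit, so this gain was built in. The added calls do not isolate spread either, since some estimates moved as well. With the covariate admp.L in BIO went from 1.31 to 2.35 and hes5.8.L from 0.94 to 2.06, while plk3.S stayed at -0.66 (log2). Whether spread alone accounts for the small number stays open.

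Gene groups were tested as hypotheses from single genes, and none was decided. For a wider p53 response beside plk2.L and ccng1.L, 65.7% of the other 35 targets had a positive value, 0 rose and 3 fell (camera p = 0.677, 0.876 with an estimated correlation). For Notch signalling, dll1.L rose by 2.58 ± 0.56 and hes4.L fell by 2.43 ± 0.29 (edgeR adjusted p = 0.0323 and 0.0029), but dll1.L did not pass without control 1, genistein 1 and genistein 3 (1.46, edgeR adjusted p = 0.102). Of the effectors other than hes4, 87.5% (21 of 24) had a negative value, and the full list of 26 had camera p = 1.85e-06, and 0.149 with an estimated correlation. For mitotic genes, the full list of 102 had 2 higher and 18 lower (camera p = 1.29e-08, 0.0144 with an estimated correlation), but it held genes whose values had been seen. With those left out, 55.7% of 79 (44) had a negative value, 0 rose and 3 fell (camera p = 0.0156, 0.263 with an estimated correlation).

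The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In genistein against control 632 genes were called and 9146 in the highest other split, with 2 of 10 as high. That split set control 1, genistein 1 and genistein 3 against the rest, which points to a structure of the samples. Genistein against BIO had 683 and 3252 (2 of 10), where genistein 1, genistein 3 and BIO 2 stood together, likewise a structure of the samples. BIO had 5 and 0 (1 of 10), Chiron 0 and 0 (10 of 10), BIO against Chiron 0 and 0 (10 of 10), and genistein against Chiron 441 and 0 (1 of 10). With the covariate genistein had 3654 and 396, BIO 184 and 0, and Chiron 117 and 1, each 1 of 10.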
